A study of Mus musculus with 19 samples.

How the data were processed

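RNA from the ventral (VP) and dorsolateral (DLP) prostate lobes of C57BL/6J mice was measured on a 3′ expression array, 1 sample per array. Per the labels' protocols, 5 mice per diet were 8 weeks old when they began 12 weeks on a control or a high fat diet (HFD). The 19 arrays fell into 4 groups by their titles: 5 of control VP, 5 of HFD VP, 5 of control DLP and 4 of HFD DLP. The labels also name the anterior lobe, which was not analysed here. The labels give 5 mice per diet and do not say which mouse each array came from, so p-values measure the spread between these samples.

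The deposited values were on a logarithmic scale taken as log10, and MAS5 is named in the submitters' processing notes. They ran from 0 to 3.99 with a median of 0.555 on each array. Sorted values were identical on all 19 arrays, so a value depends on the rank of its probe set on its array. The step that made the distributions identical is not given in the sources used here. The log base is not given either and was inferred from the hybridization controls. Their mean deposited values rose by 0.53 from bioB to bioC and by 0.74 from bioC to bioD, against 0.52 and 0.7 for log10 of the nominal concentrations. The step from bioD to cre was 0.96 against 0.6. The offset inside the logarithm was taken as 1. Every fold below rests on this base, whereas p-values do not. Because ranks set the values, a change shared by most genes would not be visible.

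Values were converted to log2 and no further normalization was applied. Of 45101 probe sets, 64 were controls and were left out. The platform annotation gave 1 symbol to 34958 probe sets, several to 932 and none to 9211. Symbols were updated through gene identifiers for 34754 probe sets, with a table of GRCm38.p6 genes used for names alone. A probe set was kept when it lay above the median of its own array on at least 4 arrays, which left 24867. The probe set with the highest mean stood for each gene, giving 11728 genes.

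Tests used limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-dependent prior) with 4 group means fitted to all 19 arrays, so that the groups shared 1 spread per gene. Adjusted p-values are Benjamini-Hochberg values at a threshold of 0.05 and are two-sided. The contrasts were HFD minus control in VP, in DLP, their difference, their average, and DLP minus VP in control mice. Gpx3 was also tested by a two-sided exact permutation test. Gene lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Of 35 lists, 34 had at least 3 tested genes. The groups, tests, lists, alternatives and the rule for named genes were set before the data were examined. The rule took, for the diet contrast in each lobe and for the lobe contrast, the 10 genes in each direction with the largest change among those past the threshold whose groups did not overlap, or the 10 smallest p-values where fewer than 10 genes passed. It took 5 in each direction for the other contrasts, all glutathione peroxidases, and up to 4 passing or 2 other members per list.

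The fit was tested on simulated data with the spread of the 11728 real genes. It recovered 76.1% of genes changed by 0.5 on the log2 scale in VP, 92.5% of those changed by 1 and 100% of those changed by 2. In DLP the shares were 50.7%, 88.1% and 98.5%. The simulated arrays of both lobes had equal spread, unlike the real ones, so these shares do not cover that difference. Each simulated contrast held 67, 67 and 66 genes changed by 0.5, 1 and 2, with noise drawn independently for each gene. The adjusted threshold is looser where many genes change, so the shares may not hold for a contrast with few changed genes or with correlated genes.

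Alternatives covered the offset, the filter, the choice of probe set, the variance prior, array weights, the replicate number as a block, the threshold, each lobe fitted alone, and each array left out. Cyclic loess, 1 weight per lobe, and a fit without 2 arrays that stood apart were added after the data had been seen. The number of arrays limits the precision.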

Results

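Gene expression was compared between mice on a high fat diet and mice on a control diet, in the ventral and the dorsolateral prostate. The series title names glutathione peroxidase Gpx3, so this gene was taken first. If that title rests on these same arrays, the tests of Gpx3 and of its family list are not independent of that choice. Lobe identity set the arrays apart most, with the first principal component holding 74% of the variance and the second 5.3%. The arrays of the ventral lobe also varied more among themselves. The median standard deviation of a gene was 0.176 in control VP and 0.172 in HFD VP, against 0.133 in control DLP and 0.116 in HFD DLP on the log2 scale.

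**Figure D1:**
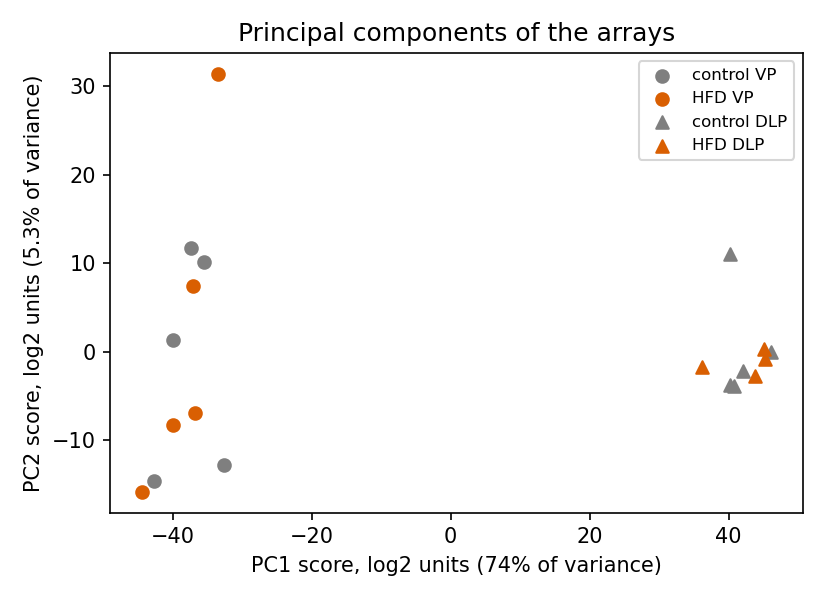
Scores of the 19 arrays on the first 2 principal components, in log2 units, with circles for VP, triangles for DLP, grey for control and orange for high fat diet. The lobes separate along the first component, which holds 74% of the variance.

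Gpx3, a secreted selenium-containing peroxidase, was lower on the high fat diet in both lobes. In VP its log2 level was 6.95 ± 0.35 (SD, n = 5) on the control diet and 5.81 ± 0.49 (SD, n = 5) on the high fat diet. The log2 difference was -1.14, or 2.21-fold lower, with a 95% interval from -1.68 to -0.61. The exact permutation p was 0.0079, the smallest that 5 against 5 arrays can give, and limma's adjusted p was 0.035. In DLP the level was 7.34 ± 0.62 (SD, n = 5) against 5.76 ± 0.16 (SD, n = 4). That difference was -1.58, or 2.99-fold lower, with a 95% interval from -2.14 to -1.02. The exact permutation p in DLP was 0.016, while limma's adjusted p over all genes was 0.064 and missed the threshold. Each control array lay above each high fat array of its lobe. With VP arrays alone in the fit, Gpx3 did not pass in VP, as no gene did (limma's smallest adjusted p 0.0507). Without control VP 3, 4 or 5, or HFD VP 1, 4 or 5, limma's adjusted p in VP missed the threshold, at most 0.072, and without control VP 4 or control DLP 2 the DLP change passed, with a lowest adjusted p of 0.021. The diet differences of the lobes were not told apart, with a difference of -0.44 and limma's adjusted p of 0.79. Gpx3 had 1 probe set past the filter.

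**Figure D2:**
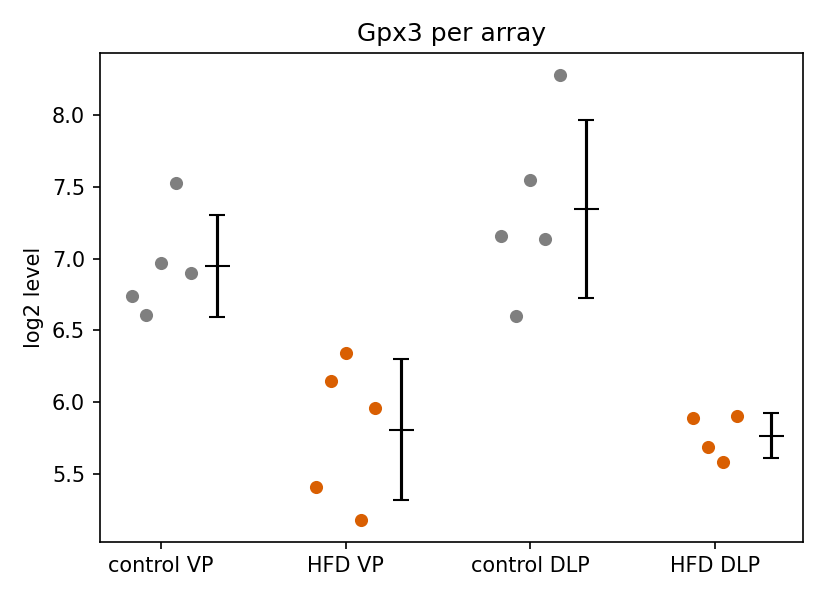
Log2 level of Gpx3 on each array, with points for arrays and bars for the mean and SD of each group. In VP the control arrays span 6.61 to 7.53 and the high fat arrays 5.18 to 6.34, and in DLP they span 6.6 to 8.28 and 5.58 to 5.9.

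Among the 6 glutathione peroxidases tested, Gpx3 was the member that passed over all genes in VP. With limma's p-values adjusted over the list alone, Gpx1 was higher, and Gpx3 and Gpx8 were lower. Exact permutation p-values adjusted over the list were 0.047 for Gpx3, 0.048 for Gpx1 and 0.064 for Gpx8. The list was chosen because the title names Gpx3, and the adjustment does not allow for that choice. Gpx1, the abundant cytosolic enzyme, differed by 0.19 ± 0.06 (SE) in VP with limma's adjusted p of 0.15. Gpx8 differed by -0.24 with an adjusted p of 0.21. Gpx4, which reduces lipid peroxides, differed by 0.20 in VP and 0.04 in DLP. Gpx2 and Gpx7 differed by 0.25 and 0.12 in VP. In DLP, none of the 6 passed over all genes, and over the list alone Gpx3 passed with limma's p-values but not with the exact permutation p, at 0.096 after adjustment.

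Averaged over both lobes, 14 genes differed by diet, 7 higher and 7 lower. This contrast treated the 2 lobes as independent, but with 5 mice per diet the arrays cannot all come from different mice. Its p-values may therefore be too small. With equal numbers taken as the same mouse, the correlation of the lobes was 0.044, but the labels do not state this link. Gpx3 had the largest change, -1.36, with an adjusted p of 0.0042. Srebf1, a transcription factor that drives lipid synthesis genes, was higher by 0.39 with an adjusted p of 0.01. The clock gene Per2 was higher by 0.43 with an adjusted p of 0.045. The hour of dissection, on which clock genes depend, was not tested. Tnpo1, a nuclear import receptor, was lower, at -0.27 with an adjusted p of 0.02. With any 1 array left out, Gpx3 and Srebf1 still passed. Per2 passed without control VP 5, HFD VP 2 or HFD DLP 3 and missed the threshold in the other 16 of 19 fits, at most 0.094. Tnpo1 missed it without control DLP 2, HFD DLP 3 or HFD DLP 4, at most 0.063. Without control DLP 2 the count was 5, and it was 5 without HFD DLP 4.

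In VP 130 genes differed by diet, 62 higher and 68 lower, among 11728 tested. Most changes were small, with a median fold of 1.33, and 2 genes fell more than 2-fold. Genes higher on the high fat diet included Ces1d, a carboxylesterase, by 0.78, Mylip, a ubiquitin ligase that targets lipoprotein receptors, by 0.71, and Srebf1 by 0.59. Others higher were Akr7a5, an aldo-keto reductase, by 0.70, Cadm1 by 0.68, Gde1 by 0.67, Hmgn3 by 0.64, Czib by 0.62, Tigd5 by 0.53 and Fgfrl1 by 0.53. The retinoic acid binding protein Crabp1 was lower, at -1.26, as were the condensin subunit Ncaph at -0.70 and the clock factor Npas2 at -0.66. Haspin was also lower. Cited2 differed by -0.68, Ier3ip1 by -0.62, Mboat2 by -0.60, the zinc transporter Slc39a6 by -0.60 and Lysmd3 by -0.59. Adjusted p-values of these genes ran from 0.00043 for Ier3ip1 to 0.043 for Lysmd3. Of the 19 fits with 1 array left out, Lysmd3 missed the threshold in 15, Cadm1 in 12, Mboat2 in 10, Cited2 in 8 and Haspin in 6, at most 0.081. Gde1 missed it without control VP 3, HFD VP 2 or HFD VP 4, Fgfrl1 without HFD VP 1, 2 or 5, Crabp1 without HFD VP 4 and Npas2 without HFD VP 5, at most 0.062. For Akr7a5 the other probe set gave -0.04. Npas2 on the high fat diet and Haspin on both diets lay below the array median of 1.85, so the size of their changes is uncertain. The circadian clock list, which holds Npas2, did not pass camera in VP, with an adjusted p of 0.14. Adjusted over the list alone, 4 of its 14 members were higher and 1, Npas2, was lower. Clock genes depend on the hour of dissection, which was not tested, so its part cannot be told apart from the diet.

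The VP count depended on how the spread was pooled with the quieter DLP arrays. A fit to VP arrays alone also has fewer arrays from which to estimate the spread. With 1 weight per lobe, 20 genes passed, all of them among the 130, and with VP arrays alone limma called 0 genes, with a smallest adjusted p of 0.0507 and 1222 genes at an unadjusted p under 0.05 against 586 by chance.

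In DLP no gene passed in limma's test, whose smallest adjusted p was 0.0638. At an unadjusted p under 0.05 there were 662 genes, against 586 by chance, and 2 genes had an adjusted p under 0.10. With DLP arrays alone limma called 0 genes, with a smallest adjusted p of 0.109 and 1113 genes at an unadjusted p under 0.05. With 1 weight per lobe 6 genes passed. The smallest p-values belonged to Ncald, a calcium sensor, with a difference of -0.54, and Gpx3. Actg1, a cytoplasmic actin, differed by 0.54, the prostaglandin transporter Slco2a1 by 0.82, Nudcd2 by 0.34, Ifitm10 by 0.50 and Inpp5b by 0.25. Iqsec3 differed by -0.51, the chaperone Hsp90aa1 by -0.46 and the kinesin Kif4 by -0.81. Their adjusted p-values lay between 0.2 and 0.36. On the high fat diet Iqsec3 and Kif4 lay below the array median.

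**Figure D3:**
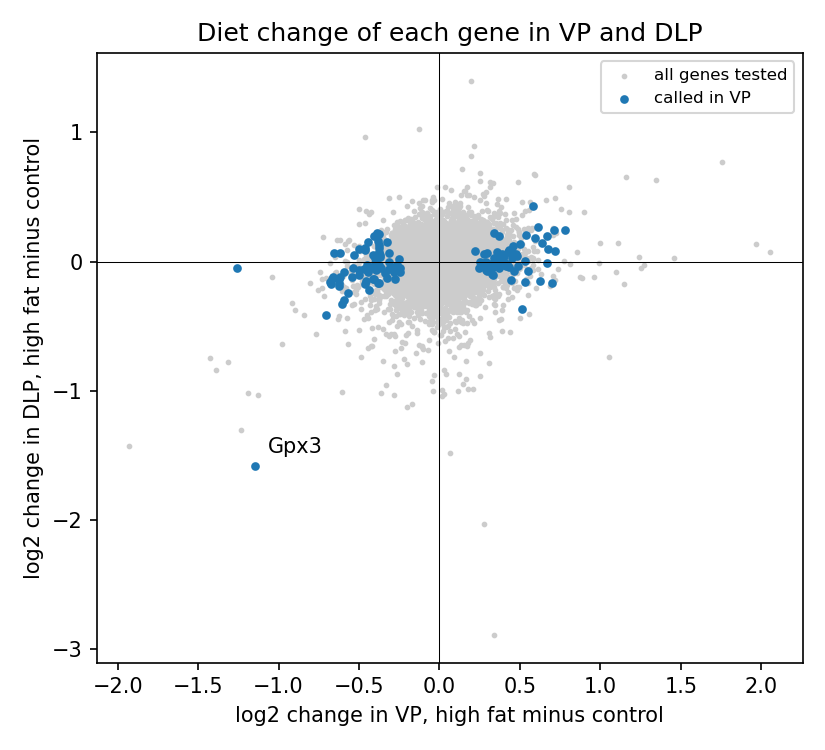
Log2 change by diet of each tested gene in VP (horizontal axis) and DLP (vertical axis), with the 130 genes called in VP in blue. Gpx3 lies apart at -1.14 and -1.58.

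The difference between the lobes in their response was itself tested, and 1 gene passed. Akr7a5 differed by -0.86 between DLP and VP, with an adjusted p of 0.023, and its other probe set gave 0.09. It missed the threshold without control VP 2, 4 or 5, HFD VP 1, 3 or 4, or HFD DLP 2, 3 or 4, at most 0.11. Across genes, which are not independent replicates, the changes in VP and DLP had a Pearson correlation of 0.17 and a Spearman correlation of 0.12. Of the 130 VP genes, 79 had the same sign in DLP, but the median ratio of their DLP change to their VP change was 0.09. The share with the same sign over all genes was not counted.

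Among the gene lists in VP, 6 of 34 passed camera at its preset correlation. Interferon response genes were higher as a list, with a median of 0.60, 18 of 19 members positive and an adjusted p of 2.1e-05. With an estimated correlation the adjusted p was 0.61. No member passed over all genes, and 5 were higher adjusted over the list alone. Ifit3 differed by 1.97 and Ifit1 by 1.46, with adjusted p-values of 0.092 and 0.15. Without control VP 4 and HFD VP 3, arrays that stood apart in hybridization controls and in immune genes, the list had a median of 0.24 and an adjusted p of 0.15. Without HFD VP 3 alone the median was 0.30 with an adjusted p of 0.027, and without control VP 4 alone it was 0.47 with 0.00064. Cell cycle genes were lower, with a median of -0.37, 17 of 18 members negative and an adjusted p of 2.1e-05, or adjusted p = 0.61 with an estimated correlation. Without both of those arrays the median was -0.64, and without control VP 3 it was -0.22 with an adjusted p of 0.0053. The score was 0.61 and 0.62 on control VP 2 and 3, but from -0.64 to -0.18 on control VP 1, 4 and 5, and from -0.71 to -0.13 on the high fat arrays. Mki67 differed by -0.91 and Top2a by -0.75, and neither passed. The 3 T cell markers tested had a median of 0.27 and did not pass camera, with an adjusted p of 0.12, but passed fry, with an adjusted p of 0.018. Their score ran from 0.15 to 0.39 on the high fat arrays and from -0.13 to 0.09 on the control arrays.

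Glutathione transferases were higher, with a median of 0.14, and 3 of 20 members were higher adjusted over the list alone. The adjusted p was 0.043, and 0.58 with an estimated correlation. Of the 6 lists past camera in VP, this was the 1 that also passed fry, with an adjusted p of 0.018. Gsta4 differed by 0.66. The list missed the threshold with the filter at the 75th percentile, and without control VP 2, 3 or 4, or HFD VP 1, 4 or 5, with a median of 0.10 and an adjusted p of 0.085 without control VP 4. Smooth muscle markers were higher, with a median of 0.18 and an adjusted p of 0.013, or adjusted p = 0.64 with an estimated correlation. Without control VP 4 the median was 0.11 with an adjusted p of 0.12, without HFD VP 3 it was 0.13 with 0.057, and without both it was 0.06 with 0.3. Other antioxidant enzymes were lower, with a median of -0.14 and Glrx2 the 1 member past the threshold at -0.38. Their adjusted p was 0.043, and 0.61 with an estimated correlation. They missed the threshold with the mean of probe sets, and without control VP 1, 4 or 5, or HFD VP 2 or 4, with a median of -0.09 and an adjusted p of 0.12 without control VP 4. Unfolded protein response genes were lower, with a median of -0.13 and an adjusted p of 0.043, or adjusted p = 0.81 with an estimated correlation. They missed the threshold without control VP 1, 2, 4 or 5, or HFD VP 3 or 4. Without control VP 4 the median was -0.11 with an adjusted p of 0.12, without HFD VP 3 it was -0.09 with 0.25, and without both it was -0.03 with 0.56. Without HFD VP 1 it was -0.24 with 0.00051. The median of the macrophage markers was 0.01. Among lists that did not pass, Col6a3 in the matrix list differed by -0.62, Hadhb in fatty acid oxidation by -0.62 and Cycs in oxidative phosphorylation by -0.38, and each passed as a gene. Of the 19 fits with 1 array left out, Hadhb missed the threshold in 14, Glrx2 in 11, Cycs in 7 and Col6a3 in 6, at most 0.092.

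In DLP, 4 of 34 lists passed camera and no member of any list passed over all genes. Cholesterol synthesis genes were lower, with a median of -0.22, 17 of 19 members negative and an adjusted p of 1.7e-08, or adjusted p = 0.41 with an estimated correlation. Of its members 7 were lower adjusted over the list alone. Fdps, a farnesyl diphosphate synthase, differed by -0.65 and Hmgcs1 by -0.50. Heat shock genes were lower, with a median of -0.29, all 10 members negative and an adjusted p of 1.8e-06, or adjusted p = 0.11 with an estimated correlation. Smooth muscle markers were higher, with a median of 0.20, all 12 members positive and an adjusted p of 1.9e-06, or adjusted p = 0.41 with an estimated correlation. Nerve markers were lower, with a median of -0.88 and an adjusted p of 0.00028, or adjusted p = 0.47 with an estimated correlation. Without control DLP 5 the median was -0.51 with an adjusted p of 0.029, and with the filter at the 75th percentile the nerve list did not pass. Their score was 0.84, 0.30 and 1.34 on control DLP 2, 4 and 5, but -1.22 and -1.26 on control DLP 1 and 3, and from -1.07 to -0.48 on the high fat arrays. Random splits of the arrays often called as many lists as the diets did, in both lobes, with 43 of 100 in VP and 52 of 100 in DLP.

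**Figure D4:**
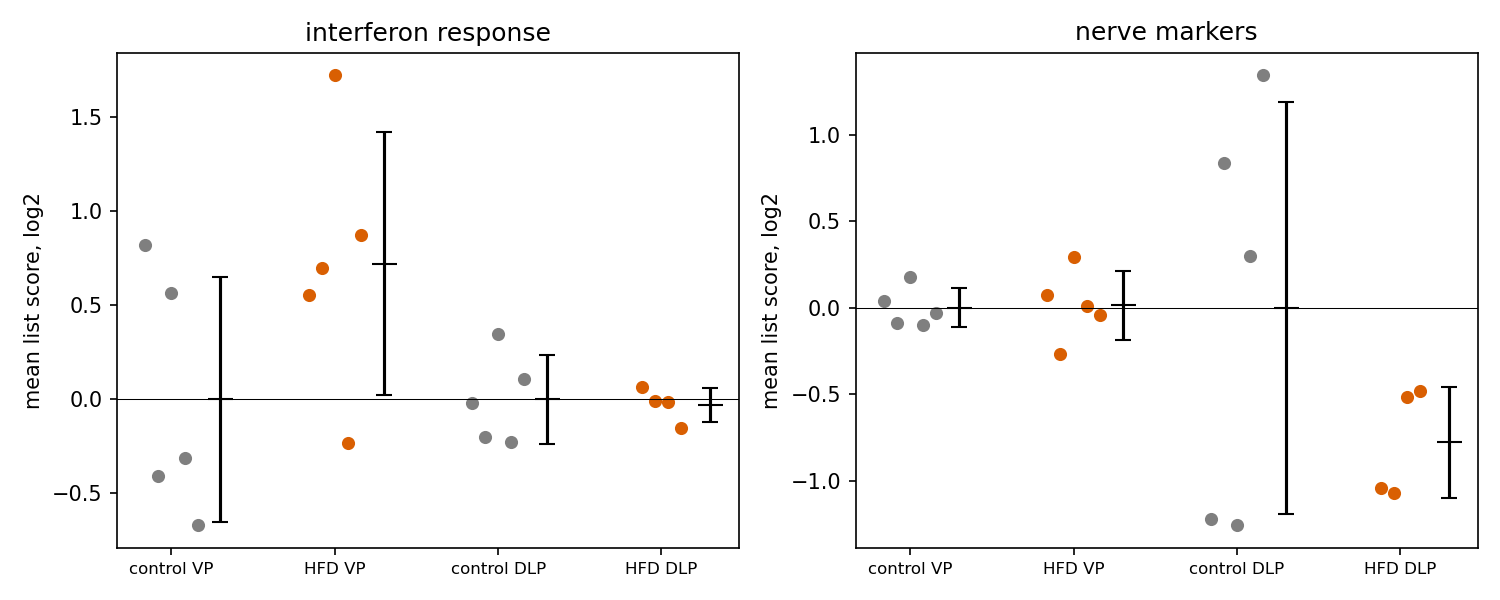
Mean log2 score of the interferon response list and the nerve marker list on each array, relative to the control arrays of the same lobe, with points for arrays and bars for the mean and SD. The interferon score of HFD VP 3 is 1.72, and control DLP arrays split in the nerve score from -1.26 to 1.34.

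The lobes of control mice differed in 6451 genes, 55% of those tested, with 3307 higher in DLP and 3144 higher in VP. Tgm4, the prostate transglutaminase, was higher in DLP by 10.80 on the log2 scale, and Pate14 by 11.17. Fcgbp was higher by 8.80, Glb1l3 by 8.11, Fgl1 by 7.62, Gsdma by 7.40 and the protease Mmp7 by 7.01. Nlrp10, Nxpe3 and Slc26a3 were higher by 6.21, 5.70 and 5.65. Genes lower in DLP included the protease inhibitor Spink5 at -6.70, Mug1 at -6.52, Nupr1 at -6.38 and Slc5a8 at -5.57. Nxpe4 differed by -5.53, Cbr2 by -5.51, Crabp1 by -5.47, the immunoglobulin transporter Pigr by -5.04, Hdac9 by -4.99 and Rnf186 by -4.92. The largest adjusted p among these 20 genes was 1.7e-08. In 13 of them the lower lobe lay below the array median, so the size of the difference is uncertain. These were Pate14, Tgm4, Glb1l3, Fgl1, Gsdma, Nlrp10, Nxpe3, Slc26a3, Mug1, Slc5a8, Crabp1, Hdac9 and Rnf186.

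Of 34 lists, 5 passed camera between the lobes of control mice. Unfolded protein response genes were higher in DLP, with a median of 0.80 and an adjusted p of 0.00012. Smooth muscle markers were higher, with a median of 0.67, an adjusted p of 0.0051 and 10 of 12 members past the threshold. Nerve markers were higher, with a median of 2.09, an adjusted p of 0.048 and 6 of 7 members past it. Much of this came from control DLP 2, 4 and 5, where Nefl was at least 3.95 and Uchl1 at least 3.75. On control DLP 1 and 3 Nefl was 1.76 and 1.69 and Uchl1 2.49 and 2.22. In control VP they ranged from 0.29 to 1.28 and from 1.77 to 2.23. Luminal epithelial markers were lower, with a median of -0.54, an adjusted p of 0.014 and 8 of 11 members lower, and interferon response genes were lower, with a median of -1.01, an adjusted p of 0.019 and 12 of 19 members lower. With an estimated correlation no list passed, with adjusted p-values of 0.77 or 0.88. By fry all 5 passed, with adjusted p-values from 1.2e-07 to 0.013, among 21 of 34 lists that fry called in this contrast. The Gapdh 3′ to 5′ difference was lower in DLP by 0.25, with an exact permutation p of 0.0079. Gpx8 was lower in DLP, at -2.09, whereas Gpx3 did not pass, at 0.39 with an adjusted p of 0.2.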

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

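The tests of single arrays, of Car3 as the only covariate, of the 2 arrays that stand apart, of macrophage markers, of group size and of lobe spread were chosen after the results were seen. The test of adipocyte genes as covariates was chosen after their levels, but before its own outcome, had been seen. The splits of the arrays were planned.

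Gpx3 was lower on the high fat diet in both lobes. Fat attached to control lobes is a candidate explanation, because Adipoq and Car3 were highest on the control arrays numbered 4. With both genes as covariates the diet change of Gpx3 was -1.41 ± 0.31 (SE), against -1.35 without them. Adipoq lay above the array median on 1 of 19 arrays and Car3 on 12, and with Car3 alone the change was -1.30 ± 0.32. Car3 itself was lower on the high fat diet, at -1.19 in VP and -1.01 in DLP. The 5 adipocyte markers tested did not pass camera as a list, with a median of -0.14 in VP and 0.01 in DLP. The fits left most of the Gpx3 change in place, but they cannot decide on fat. Adipoq lay mostly below the array median, and Car3 is 1 gene that differed by diet itself. A part played by fat is not excluded. With 1 array left out the smallest change was -0.99 ± 0.25 (SE) in VP, without HFD VP 4, and -1.35 ± 0.21 in DLP, without control DLP 5, so no single array carried most of it. Because the diets do not overlap, leaving out an array could not have turned the sign or ended the exact test. The limma call was less stable. In VP it was lost without control VP 3, 4 or 5, or HFD VP 1, 4 or 5 (adjusted p at most 0.072). In DLP it was gained without control VP 4 or control DLP 2 (lowest 0.021). The VP call also needed the DLP arrays in the fit, because no gene passed with VP arrays alone. A response to diet stays a hypothesis found and tested on the same arrays.

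The interferon response list was higher in VP. Its mean score differed by 0.72 ± 0.43 (SE) by diet, and by 0.39 ± 0.44 without control VP 4 and HFD VP 3. The part played by these 2 arrays cannot be told apart from the diet, because the error is as large as the change. More macrophages may also contribute; the score of their markers differed by -0.02 ± 0.4, which is too wide to decide. Diet stays open as untested.

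The test called 130 genes in VP and 0 in DLP. The array fewer in DLP is not a sufficient explanation, because at least 70 genes passed in VP with any 1 high fat VP array left out. The larger spread of VP arrays may account for much of the contrast, since 20 genes passed in VP and 6 in DLP with 1 weight per lobe, and 47 and 5 with a weight per array. That weighted count of 20 in VP lies between the values that the spread or a lobe difference would give, so it cannot tell them apart. With each lobe fitted alone 0 genes passed in either, and 1222 in VP and 1113 in DLP had an unadjusted p under 0.05. The contrast of 130 and 0 was thus not seen without the shared spread. Those fits hold fewer arrays, so a lobe difference is not excluded. The response of the lobes itself differed in 1 gene.

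Splits of the arrays were counted for each result, 100 per result with the real split among them. In VP 4 of 100 splits gave at least 130 genes, which is under 0.05. Only 100 of 126 possible splits were drawn, so those left out could take the share past it, and chance was not firmly excluded. Another split gave 454, which points to a structure among the VP arrays other than diet. In DLP all 100 gave at least 0, as any split must, so this count says nothing about chance. The highest other count in DLP was 39. For the difference between lobes 5 of 100 gave at least 1 gene, with a highest other of 178, and chance was not excluded. For the average over lobes 1 of 100 gave at least 14, with a highest other of 2. For the lobe contrast 1 of 100 gave at least 6451, with a highest other of 1458. No other split drawn reached either count. These splits relabelled arrays rather than mice, so they weigh against chance only as far as arrays are independent. For the lists chance was not excluded, with 43 of 100 splits giving at least 6 in VP (highest other 15) and 52 of 100 giving at least 4 in DLP (highest other 10).

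Akr7a5 had a diet change that differed by -0.86 between DLP and VP, and it missed the threshold in 9 of the 19 fits with 1 array left out, at most 0.11. By camera, the interferon response list differed between lobes with a median of -0.67 and the cell cycle list with a median of 0.30, and neither passed with an estimated correlation (adjusted p = 0.78 for both).

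A single array lay far from its group in 22 of 236 groups of values, where chance gives about 12. On control VP 4 the older hybridization controls were at 3.20 against 7.04 to 7.44 on the other arrays of the group, Fgfrl1 at 2.82 and Haspin at 1.46. On HFD VP 3 the macrophage score was 1.21, the Gapdh 3′ to 5′ difference -0.41 and the older hybridization controls 7.04. Control VP 1 had newer hybridization controls at 7.69 and an IGF and insulin signalling score of 0.18, and control VP 3 an unfolded protein response score of -0.25. HFD VP 1 had a fatty acid oxidation score of -0.13, HFD VP 2 a glutathione transferase score of 0.03 and a red blood cell score of 0.63, and HFD VP 4 Cited2 at 6.93 and a circadian clock score of 0.28. Control DLP 1 had Lysmd3 at 5.65, an inflammation score of 0.99 and an acute phase score of 0.91. Control DLP 2 had Crabp1 at 1.80 and control DLP 4 an androgen response score of 0.08. HFD DLP 1 had Slc39a6 at 4.13, and HFD DLP 2 had Ncaph at 3.78 and a prostate secretory score of 0.48.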

How the results depend on the processing

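Cyclic loess, 1 weight per lobe and the fit without control VP 4 and HFD VP 3 were chosen after seeing the data. Quantile normalization and median centring moved no value and are void. Gpx3 has no other probe set past the filter, and a fit to 1 lobe cannot give the difference between lobes, so these were not run. Gpx3 kept its direction under every alternative run. With other offsets or an array left out this was fixed in advance, because the diets do not overlap in either lobe. With 1 array left out its change ranged from -1.28 to -0.99 in VP and from -1.77 to -1.35 in DLP. The lobe contrast ranged from 6099 to 6584.

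The VP count of 130 was 78 with no filter, 209 with the filter at the 75th percentile, 47 with the mean of probe sets, 83 with no trend, 47 with array weights, 20 with 1 weight per lobe, 0 with VP arrays alone and 321 at adjusted p under 0.10. With 1 array left out it ranged from 70 to 148. It was 83 without control VP 2, 86 without control VP 3, 80 without control VP 5, 85 without HFD VP 1, 81 without HFD VP 4, 70 without HFD VP 5, 86 without HFD DLP 1 and 83 without HFD DLP 4. The DLP count of 0 was 1 with no filter, 5 with array weights, 6 with 1 weight per lobe and 2 at adjusted p under 0.10, and ranged from 0 to 2 with 1 array left out, with 2 without control VP 4 or control DLP 3 and 1 without control DLP 2. The count for the difference between lobes was 0 with the mean of probe sets, 2 with all probe sets and 3 without both arrays that stand apart, and ranged from 0 to 2; it was 0 without control VP 2, 4 or 5, HFD VP 1, 3 or 4, or HFD DLP 2, 3 or 4, and 2 without control DLP 4. The average over lobes gave 5 with the mean of probe sets, 44 with array weights, 89 at adjusted p under 0.10 and 30 without both arrays, and ranged from 5 to 21, with 9, 5 and 8 without control DLP 1, 2 and 4, and 9, 6 and 5 without HFD DLP 1, 3 and 4.

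VP lists numbered 0 with an estimated correlation, 2 by fry and 3 without both arrays, and ranged from 2 without control VP 4 to 10 without HFD VP 3, with 3 without HFD VP 4. With the filter at the 75th percentile the circadian clock list passed in VP in place of the glutathione transferases, and in DLP the unfolded protein response list in place of the nerve markers. Other antioxidant enzymes did not pass in VP with the mean of probe sets. DLP lists numbered 0 with an estimated correlation, 0 by fry and 6 with 1 weight per lobe, and ranged from 4 to 6.

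Between diets in VP, 3 of 5 same-numbered pairs of arrays had a correlation over 0.1 (from -0.1 to 0.46), and 1 of 4 in DLP (from -0.15 to 0.17). Between lobes it was 2 of 5 in control mice and 2 of 4 on the high fat diet. Not all did, so the numbers were not taken as pairs, though pairing is not ruled out. With the replicate block, the difference between lobes gave 0 genes and DLP lists numbered 7, and Cadm1, Col6a3, Glrx2, Lysmd3 and Mboat2 missed the threshold in VP. Crabp1 missed it there with no offset. The paired sign flips of Gpx3 gave -1.14 with an exact permutation p of 0.062 in VP and -1.35 with 0.12 in DLP, where 5 or 4 pairs cannot pass 0.05. Gpx7 in DLP was 0.02 under the replicate block and Gpx2 in DLP was 0 with no offset.

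Among named genes with 1 array left out, 5914 values kept their call, 182 lost it, 15 gained it and 26 turned sign. None that turned had passed the test. In VP the ranges were Ctss -0.11 to 0.47, H2-Ab1 -0.02 to 0.54, Ighm -1.21 to 0.26, Jchain -0.33 to 0.88, Rps18 -0.01 to 0.39, Saa3 -1.28 to 0.24 and Slc4a1 -0.02 to 0.47. In DLP they were Gpx2 -0.11 to 0.20, Gpx7 -0.09 to 0.05, Irf7 -0.39 to 0.03, Lcn2 -1.08 to 0.03, Lyz2 -0.57 to 0.03, Saa3 -1.42 to 0.21, Slc4a1 -0.17 to 0.16 and Svs4 -0.26 to 1.06. Gpx4 between lobes ranged from -0.04 to 0.10.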

Other observations

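Neuronal genes varied widely among control DLP arrays. Snap25, a synaptic vesicle fusion protein, was at 5.35, 4.48 and 6.00 on control DLP 2, 4 and 5 and at 1.88 and 1.64 on control DLP 1 and 3. The neuropeptide gene Vip was at 7.38, 5.86 and 6.47 on the former and at 2.14 or lower on the latter. On the high fat DLP arrays Vip ranged from 1.94 to 3.42.

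Immune genes stood high on HFD VP 3, where Gbp2 was at 6.82 and Iigp1 at 7.61. On the other high fat VP arrays Gbp2 ranged from 2.92 to 3.75 and Iigp1 from 3.16 to 4.31. Lcn2 was at 8.21 on control VP 1 and 7.87 on control DLP 1. Car3, an adipocyte-rich carbonic anhydrase, was at 3.79 on control VP 4 and 4.05 on control DLP 4, the highest of each lobe. By diet Car3 differed by -1.19 in VP, with an exact permutation p of 0.0079, the smallest that 5 against 5 arrays can give. It was 0.095 after adjustment over 12 tests, which 1 value at that minimum could not pass. With limma's p-values adjusted over the 5 adipocyte markers alone, Car3 was lower in both lobes and Plin4 was higher in VP.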
